A study of Bos taurus with 100 samples.

How the data were processed

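Single cells of cultured bovine (Bos taurus) retinal microvascular endothelial cells, the cells that line the small vessels of the retina, were captured on a microfluidic chip (Fluidigm C1) at passage 3, in 2 runs of the capture instrument, and sequenced. Per the labels, 49 cells came from run 1 and 51 from run 2, and libraries were made from the amplified cDNA with a modified Nextera XT protocol scaled down with an acoustic dispenser. Per the submitters' processing notes, the tools included bcl2fastq, FastQC 0.11.3, STAR 2.5.3a, MultiQC and HTSeq 0.6.1p1, and the genome build was UMD3.1. The options of these tools were not given in the sources used here.

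The authors deposited 1 table of raw read counts per run, with 24616 Ensembl gene identifiers in the same order in both. No row lacked a gene identifier. The counts are reads, without molecular identifiers, so intervals on them cover counting error only. The 2 tables do not pair identifiers with gene names. None of the identifiers (0 of 24616) matched the RefSeq gene table used here, which is of another assembly (ARS-UCD2.0) and holds 37063 genes. For this reason the 31 gene lists fixed before the data were examined (cell type markers and pathways), the cell cycle calls, the share of mitochondrial reads and the naming of clusters by markers were not computed. At most 2 identifiers are given in each direction.

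Every GEO sample is 1 cell, and the labels name no animal, donor or culture. Cells are not replicates, so each run was taken as 1 sample: no test between the runs was made, and no p-value or standard error is given. Counts of the cells of a run were summed and divided by the summed total and expressed as CPM (counts per 1e6 reads of the run), with exact Poisson 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals. For the log2 ratios, a gene with fewer than 3 counts in a run was set to a floor of 3 counts over that run; a fold against a run with 1 or 2 reads is given from the reads themselves, with its counting interval. Fold differences between the runs are log2 ratios of run 2 over run 1.

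The rule for genes given by identifier was fixed before the data were examined. It takes genes with at least 20 CPM in the higher run and a read in at least 25% of its cells. They are ranked by the smallest of 3 absolute log2 ratios, which must share a sign: from summed counts, from the mean of the cells' CPM, and from summed counts without the cell that holds most of the gene's reads. The rule also asked for a gene symbol, which could not be applied, and 12 genes per direction, of which 2 are given.

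Clustering used log2(CPM + 1) of the 1000 genes with the highest variance within runs above a lowess trend (fraction 0.3) with the mean, among genes with a read in at least 10 cells. Values were centred within each run and reduced to 10 principal components. Ward clustering was cut at 2 to 6 clusters by the highest mean silhouette. Since cells were centred, clusters are relative to the run's mean. Doublets were not called.

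To compare cells at equal depth, reads were drawn without replacement to 300000 per cell, the planned depth, which left out 7 cells of run 1 and 3 of run 2. A second draw to 47000 reads kept all cells and was chosen after seeing the data.

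The following measures were also chosen after seeing the data. A list of 50 genes was made for each run, by the largest difference between the runs in the share of cells with a read. Each cell was scored on lists made without it. Dropout between 2 cells was the share of genes with at least 5 reads in 1 cell at 47000 reads that had no read in the other, averaged over both directions. Wells were read from the row letter and column number in the sample titles. Neighbouring wells are those of the same run and row in adjacent columns. Wells above one another in a column were counted among the other pairs. Within each run, cells were split 20 times into 2 random groups of equal size to describe how much summed profiles vary without a change of run.

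On simulated counts for all 24616 genes with the real depths, 200 genes were changed between the runs, 50 at each size. The mean recovered log2 ratios were 1.00 (SD 0.04) for a planted 1, 1.99 (SD 0.04) for 2, -1.00 (SD 0.06) for -1 and -2.00 (SD 0.07) for -2. They were taken relative to the median of the unchanged genes, a step not applied to the reported ratios. All cells of a run were drawn from the same profile here, so the SDs hold no variation between cells. With the number of clusters set to 2, clustering separated 2 planted kinds of cell with an adjusted Rand index of 1. The choice of that number by silhouette was not part of this check. The planted kinds differed by 1 fixed fold in a set of genes, so smaller differences between kinds were not checked. With no planted kinds, the highest mean silhouette was 0.0717 at equal depths but 0.676 at the real depths, so this measure can be high from depth alone.

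The alternatives planned were equal weight per cell, thinned cells, TMM and median-of-ratios factors, quality limits of 100000 reads and 2000 genes, other detection and expression minimums, and other settings of the clustering. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors.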

Results

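The data comprised read counts for 100 single retinal microvascular endothelial cells in 2 runs of the capture instrument, 49 cells in run 1 and 51 in run 2. Run 1 held 20723781 reads assigned to genes and run 2 held 103422821. A run 1 cell had a median of 418501 reads (range 230083 to 798667) and a run 2 cell 1964952 (range 47118 to 3693862). The design text names the 2 runs and no treatment, so the questions addressed were how far the runs resembled each other and how the cells varied within them. Each run was 1 sample, without replicates of animal or culture, so differences between the runs have no replicate check.

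Most of the difference in detected genes between the runs went with depth. As deposited, a median of 6072 genes (quartiles 5853 and 6485) had a read in a run 1 cell and 7148 (quartiles 6638.5 and 7777) in a run 2 cell, a difference of 1076. With cells thinned to 300000 reads, the medians were 5930 and 6228.5, a difference of 298.5. In all, 14968 genes had a read in at least 1 cell, 13890 of them in run 1 and 13459 in run 2. A core of 1055 genes had a read in every one of the 100 cells and took 58.8% of all reads. Such a number depends on the poorest cells. In run 2, 1565 genes had a read in every cell, and 1811 with cells 74 and 87 left out. At least 50% of the cells of each run had a read of 5364 genes.

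**Figure D1:**
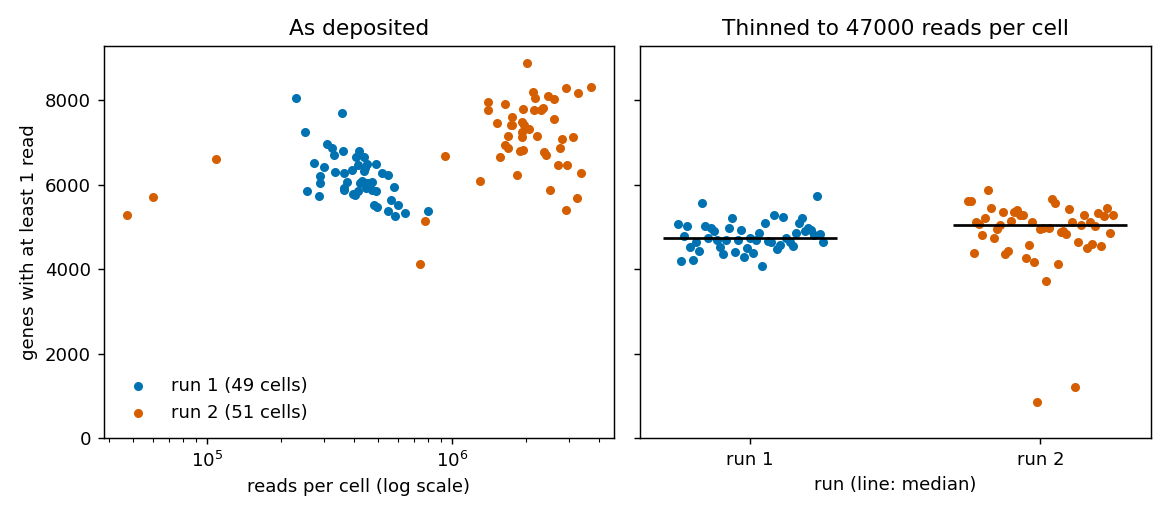
Genes with at least 1 read against reads per cell on a log axis (left, 1 point per cell) and genes with a read after thinning to 47000 reads (right, lines are medians). The run medians of 6072 and 7148 genes as deposited come closer after thinning, to 4752 and 5046, and 2 run 2 cells lie far below, at 847 and 1217.

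The summed profiles of the runs differed more than random groups of cells of 1 run did. Among 6378 genes with at least 20 CPM in a run, the median absolute log2 ratio between the runs was 0.59 (quartiles 0.27 and 1.19). Across these genes, which are not independent replicates, the correlation of log2(CPM + 1) was 0.640 (Pearson) and 0.695 (Spearman). Without run 1 cells 12 and 47, described below, the Pearson value was 0.606. Over 20 random splits, the median absolute log2 ratio ranged from 0.26 to 0.30 between groups of run 1 cells, from 0.27 to 0.30 between groups of run 2 cells and from 0.63 to 0.69 between groups of different runs. The corresponding mean Pearson correlations were 0.933, 0.933 and 0.609. These splits describe variation among cells and are no test of the runs. The median log2 ratio was 0.18, and median-of-ratios scaling shifted every log2 ratio by -0.11.

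Some genes had a read in most cells of 1 run and few or no reads in the other. ENSBTAG00000018563 had 312.7 CPM in run 1 (Poisson interval 305.2 to 320.4) and a read in 47 of 49 cells (95.9%, exact interval 86.0% to 99.5%). Its median over run 1 cells was 195.8 CPM. In run 2 it had 0 reads in 51 cells. Against the floor of 3 counts over the run, 0.029 CPM, it was at least 10781-fold lower in run 2, and the exact 2-sided 95% bound was 8765-fold. ENSBTAG00000007596 had 218.4 CPM in run 1 (interval 212.1 to 224.9), with a read in 47 cells and a median of 185.0 CPM per cell, and 2 reads in run 2. The ratio was 11296, with a counting interval of 3125 to 93304. In the other direction, ENSBTAG00000004594 had 156.4 CPM in run 2 (interval 154.0 to 158.9) and a read in 49 of 51 cells (96.1%, interval 86.5% to 99.5%), with a median of 88.2 CPM per cell and quartiles of 9.80 and 218.6. ENSBTAG00000022020 had 159.7 CPM in run 2 (interval 157.2 to 162.1) and a read in 41 cells (80.4%, interval 66.9% to 90.2%). Its median per cell was 21.7 CPM, with quartiles of 0.515 and 121.2, so its summed level rested on a minority of the cells. Both had 0 reads in run 1. Against the floor there, 0.145 CPM, they were at least 1081-fold and 1103-fold higher in run 2, with exact 2-sided bounds of 879-fold and 897-fold. For the 3 genes with 0 reads in every cell of a run, a row lost from that run's table was not excluded. With cells thinned to 300000 reads, the log2 ratios of these genes, which rest on the floor, came to -10.52, -10.08, 9.36 and 9.21.

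**Figure D2:**
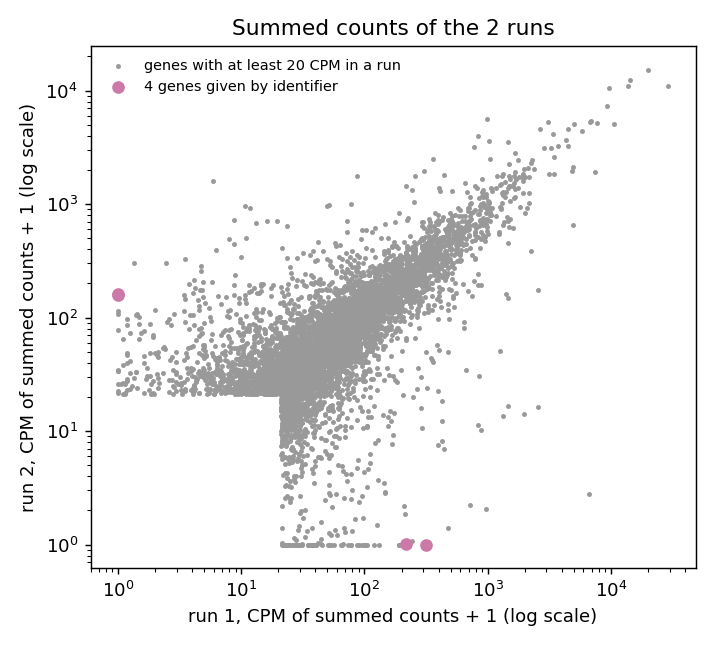
Summed CPM + 1 of run 2 against run 1 on log axes, 1 point per gene with at least 20 CPM in a run. The larger points are the 4 genes given by identifier, which lie along the axes, at 312.7 and 218.4 CPM in run 1 or 156.4 and 159.7 CPM in run 2.

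Lists of the 50 genes that best told the runs apart, chosen after seeing the data, were applied to each cell with that cell left out. A run 2 cell had a read in 40 to 50 genes of the run 2 list and in 0 to 8 of the run 1 list. Of the run 1 cells, 47 had a read in 37 to 49 genes of the run 1 list and in 0 to 5 of the run 2 list. The remaining run 1 cells were cells 12 and 47. Run 1 cell 12 had 6 genes of the run 1 list and 43 of the run 2 list. Its median correlation of log2(CPM + 1) across all 24616 genes was 0.718 with run 1 cells and 0.764 with run 2 cells. These genes include many without a read in any cell. Correlations between cells are therefore not comparable with that between the runs over 6378 genes. Run 1 cell 47 had 48 genes of the run 1 list and 38 of the run 2 list. It had the most genes with a read in run 1, 8055, at the lowest depth of that run, 230083 reads.

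**Figure D3:**
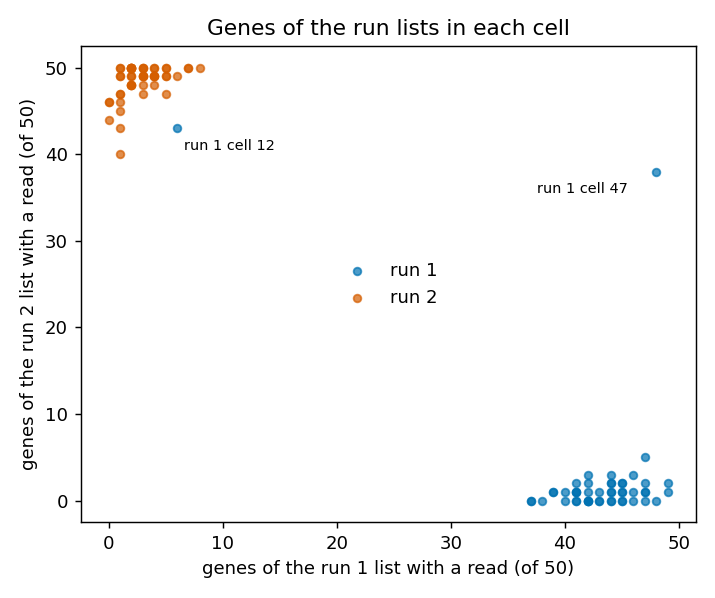
Number of genes of the run 2 list with a read against that of the run 1 list, 1 point per cell, of 50 genes each, with each cell left out of the choice of its lists. Run 1 cell 12 lies at 6 and 43, and run 1 cell 47 at 48 and 38, apart from the 47 other run 1 cells.

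Clustering within runs gave no firmly separated groups. The mean silhouette was highest at 5 clusters, at 0.208, and lay between 0.146 and 0.185 at the other numbers. Cluster 1 held 53 cells, which were 38 of the 49 run 1 cells (77.6%, exact interval 63.4% to 88.2%) and 15 of the 51 run 2 cells (29.4%, interval 17.5% to 43.8%). Cluster 2 held 37 cells, 11 of run 1 (22.4%, interval 11.8% to 36.6%) and 26 of run 2 (51.0%, interval 36.6% to 65.2%). The 11 included run 1 cells 12 and 47. At 47000 reads, the median number of genes with a read was 4685.5 in cluster 1 and 5098 in cluster 2 for run 1 cells, and 4743 and 5290 for run 2 cells. Clusters 3, 4 and 5 held 6, 2 and 2 cells, all of run 2. Cluster 3 included cells 74 and 87, which had most reads in a few genes. Cluster 4 was cells 70 and 71 and cluster 5 was cells 75 and 76, pairs in neighbouring wells with near-identical profiles, so these cells shaped the choice of 5 clusters. The adjusted Rand index with this clustering was 0.646 to 0.915 with other numbers of genes, components or clusters, k-means, thinned cells and quality limits. It was 0.362 without centring. With the cells of clusters 3 to 5 left out, which also gave 2 clusters, it was 0.0968. The run 1 share of cluster 2 was 0% without centring and 6.12% with 1 cluster more. The shares are values of this clustering and are not read as a difference in makeup between the runs. Across 4281 genes not used for clustering, the log2 ratios between clusters 1 and 2 in the 2 runs correlated at 0.265 (Pearson) and 0.192 (Spearman), and 56.8% had the same sign. With cluster labels shuffled 20 times within runs, the Pearson value lay between -0.0546 and 0.0787. The clusters were cut over both runs together and differed in genes with a read in both. Some agreement therefore follows from how the clusters were made, which shuffled labels do not take into account. The correlation is no separate support for the clusters.

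Cells 74 and 87 of run 2 had most reads in a few genes. The 50 leading genes of each took 97.6% and 92.4% of reads, against 16.8% to 25.9% in the other run 2 cells. The same 10 genes led both cells and took 87.9% and 84.0% of reads, against a median of 4.89% and at most 11.0% in the others.

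Several cells in neighbouring wells of run 2 had near-identical profiles. Dropout had a median of 17.3% over all 4950 pairs of cells. It was 1.21% between run 2 cells 68 and 69, 1.25% between cells 50 and 51 and 1.36% between cells 75 and 76. Their Pearson correlations across all 24616 genes were 0.992, 0.993 and 0.990. Cells 97 and 98, 94 and 95, 89 and 90, and 70 and 71 followed with dropout of 1.85%, 2.28%, 2.74% and 3.80%. The lowest value of any other pair was 5.84%. All but cells 70 and 71 lay in columns 1 and 2 of their row, and these were all 6 pairs that run 2 had in those columns. Of its 25 other pairs of neighbouring wells, 1 was among the 7, which were set by dropout. The 6 pairs in columns 5 and 6 had dropout of 3.80% to 21.7%. By correlation, cells 84 and 85 of these columns reached 0.879. The highest correlation of run 2 cells not in neighbouring wells was 0.858. The chi-square per degree of freedom of the counts of the 7 pairs was 3.97 to 54.2, highest for cells 70 and 71. It was 10.6 for cells 68 and 69, 8.02 for cells 50 and 51 and 12.4 for cells 75 and 76. Cells 50, 51, 68 and 69 against cell 57, their next closest by dropout, had 38.9, 53.3, 47.3 and 47.5. Cells 70 and 71 were thus less alike by this measure, which also depends on depth. The measure is set against counting error only, which amplification also exceeds. By itself it does not tell whether the libraries of a pair came from separate cells. Every cell was counted separately, as labelled. The 26 pairs of neighbouring wells in run 1 had dropout of 7.31% or more.

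**Figure D4:**
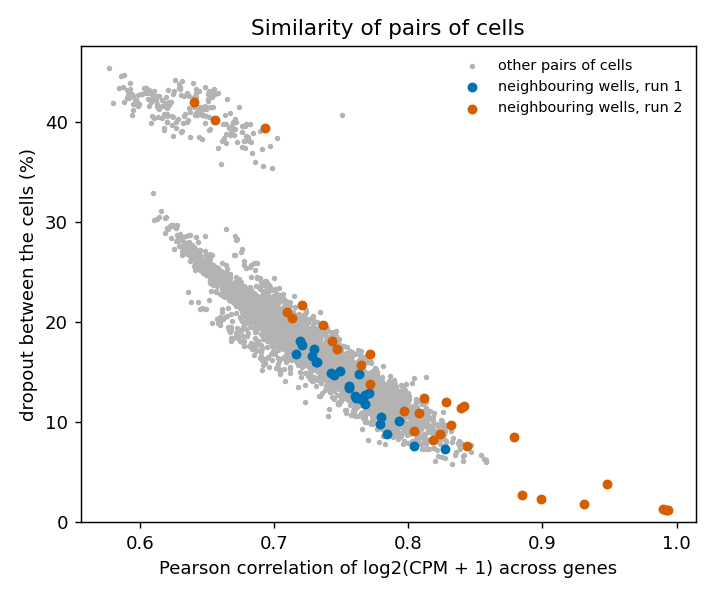
Dropout in percent against the Pearson correlation of log2(CPM + 1) across all 24616 genes, 1 point per pair of cells. The 7 pairs of neighbouring run 2 wells at 1.21% to 3.80% lie below all other pairs, which start at 5.84%.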

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

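The alternatives that leave out chosen cells, thin to 47000 reads, or regress out genes per cell were chosen after seeing the data. The median absolute log2 ratio between the runs, 0.59, was 0.589 with equal weight per cell, 0.586 with thinned cells, 0.584 with TMM and with median-of-ratios factors (0.5838), and 0.604 without run 1 cells 12 and 47. It was 0.641 at a minimum of 10 CPM and 0.793 at 1 CPM, minimums that admit genes with fewer reads. The difference in genes with a read per cell, 1076, was 157 at 10 CPM or more, 298.5 in thinned cells and 294 at 47000 reads, where depth is equal. The share of run 1 cells in cluster 1, 77.6%, was 98.0% without centring. The share of run 2 cells in it, 29.4%, was 0% without centring, 47.1% with 5 principal components, 50% without the shallower cell of each close pair, 73.2% without the cells of clusters 3 to 5 and 84.3% with genes per cell regressed out; the cause was not tested. In these last settings 1 new cluster held most cells of both cluster 1 and cluster 2, so the values are shares of that joint cluster. The share of run 1 cells in it was 75.5% and 83.7%, so the order of the runs seen in cluster 1 was not kept with genes per cell regressed out, nor that in cluster 2 without clusters 3 to 5. Of these main results, 30 further values stayed within the counting interval or within 1.5 times. The 4 identifiers kept their direction in all alternatives run. This was all but fixed in advance, since the rule took the largest ratios and asked for the same sign with equal weight per cell. Not run, since identifiers could not be matched to names, were the alternatives for gene lists, cell cycle and mitochondrial share. The planned clustering was to leave out genes of the fixed lists. None could be matched, so the alternative that keeps them is the clustering reported. No paired analysis was possible because the runs share no cell numbers. Depth limits detection most in run 2 cells 90, 95 and 98, with 47118, 60037 and 109329 reads.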

Other observations

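The tests on thinned cells, on run 1 cells 12 and 47 and on columns of wells were chosen after the results were seen. Those on reads in the other run, on cells rich in genes, on genes found in 2 cells and on genes per cell were set before their values were seen, for patterns already noticed. The test on reads in the other run replaced an earlier form and was rewritten on the whole lists. Earlier tests on neighbouring wells were dropped, since how the pairs were picked fixed their outcome. No biological explanation was tested, since the labels give no donor, culture or treatment for either run.

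Genes found in 1 run are not accounted for by depth: the median run 2 cell, thinned to 300000 reads, still had a read in 47 of the 50 genes of the run 2 list. Rows lost from 1 of the tables are argued against for the 52 of the 100 list genes that had a read in the other run with run 1 cells 12 and 47 left out, a number just past the bound of 50 set for it. Of the 28 run 2 list genes with none there, 26 had a read in cell 12 or 47, in the same table, while a lost row stays open for the other 2 and for the 20 run 1 list genes without a read in run 2. A minor admixture of run 2 reads is argued against for cell 12, which had only 6 genes of the run 1 list, whereas a wrong label or a cell of the other kind stays open. Cell 47 may hold material of both kinds, as a hypothesis. Its list levels were 0.728 and 0.289 of the run medians, a sum of 1.02. Yet its run 1 list level, 5646 CPM, lay within the spread of other run 1 cells. Run 1 cell 35, with 2 genes of the run 2 list, had 4665 CPM. The sum therefore does not show dilution, and it does not separate a doublet from carry-over. Differences of donor, culture or batch between the runs cannot be told apart.

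Among the near-identical neighbouring wells, cells rich in genes do not explain cells 70 and 71 or cells 75 and 76. At equal depth these had 4273, 4576, 4947 and 4974 genes with a read, under the run 2 median of 5046. For the other close pairs the test cannot decide, since 9 of the 14 cells reached that median. Both cells reached it in the pairs 50 and 51, 68 and 69, 89 and 90, and 97 and 98. Separate cells of like state, wherever they lie, are argued against for columns 1 and 2 of run 2, a split noticed before its bounds were set. There 6 of 6 pairs were close by dropout, against 1 of 25 other neighbouring pairs. Separate cells stay open for cells 70 and 71 and for cells 84 and 85. Material shared between wells, or cDNA of 1 cell in both, was tested on 623 genes found in exactly 2 run 2 cells that took no part in the dropout measure. In 4 of the 7 pairs the cells shared at least 3 times as many of them as either shared with any other run 2 cell, between the bounds of 2 and 5 set beforehand, and each pair that missed includes a cell of 47118, 60037 or 109329 reads. Cells 50 and 51 shared 32 such genes and cells 68 and 69 shared 24, against at most 1 with any other cell. Cells 75 and 76 shared 10 against at most 1, and cells 70 and 71 shared 10 against at most 2. Of the pairs that missed, cells 97 and 98 shared 10 against 6, cells 94 and 95 shared 3 against 3, and cells 89 and 90 shared 2 against 2. Shared material stays open, without a test of the step at which it arose.

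The split into clusters 1 and 2 may follow the number of genes with a read per cell, as a hypothesis. With that number regressed out, the adjusted Rand index over their 90 cells fell to 0.104, under the bound of 0.2 set beforehand, and was 0.0877 without cells 74 and 87. The regressed fit had 4 clusters, and the index was 0.0524 with 5. Controls were added after this was seen. With nothing regressed out and 4 clusters the index was 1, which shows only that this cut did not merge clusters 1 and 2. It was 0.635 to 1 over 20 fits with the number of genes shuffled within runs and regressed out. Yet with nothing regressed out, leaving out the 10 cells of clusters 3 to 5 gave 0.0968 and leaving out 10 random cells of clusters 1 and 2 gave 0 to 1 over 20 draws (median 0.808), so a fall of this size also came from which cells were included. What sets the number of genes per cell, technical yield or cell state, was not tested.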
